A study of Solanum lycopersicum with 6 samples.

How the data were processed

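The series holds 6 RNA-seq libraries from tomato (Solanum lycopersicum) fruit, 3 from wild type and 3 from an SlLBD40 knockout line, all given the time point of 25 days after anthesis. Per the labels' protocols, total RNA was extracted with TRIzol and 3 biological replicates were taken per genotype. The labels do not say whether these were separate plants or pools, so p-values measure the spread between these libraries.

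Gene expression was read from one deposited table of 40229 gene models, of which 6154 carry noncoding identifiers. The header gives no unit. The values of each library sum to between 987932 and 994646, and they were therefore treated as TPM, transcript abundances scaled to 1e+06 per library, as deposited by the authors. The submitters' processing notes name TopHat2, HISAT2, StringTie and Cufflinks, without roles or versions. The genome build and annotation release are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval was computed. An exact 0 can be a failed estimate in such a table, since 6 genes were listed at 0 in exactly 1 library while above 20 TPM in all others. Genes listed at 0 in a whole group are given by library, without a fold change. Gene names and descriptions are those of the table; 0 of its identifiers matched the reference gene table, which was not used.

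The table's columns name the genotype and are numbered from 1 to 3 within it, unlike the sample titles. Columns were therefore assigned to a genotype only, and "wild type 1" or "knockout 1" below is the number of a column. The labels place all 3 wild-type samples in 1 sequencing lane and 2 of the knockout samples in another, and give no lane for the remaining knockout sample. With 0 lanes holding both genotypes, lane and genotype cannot be told apart. The sample titles also start with a different prefix in each genotype, whose meaning is not given, and the series title speaks of several fruit stages. If lane or prefix goes with a fruit stage or another difference in growth or handling, that difference is confounded with genotype in every comparison, for single genes and for lists.

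Genes with at least 1 TPM in at least 3 libraries were kept, which left 18368, including 1189 noncoding ones. Knockout was compared with wild type by limma 3.58.1 in R 4.3.3, on log2(TPM + 1), with a mean-variance trend and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low values. Counts of genes with a higher or lower mean use the same scale. A two-sided exact permutation test of 3 against 3 libraries cannot give a p below 0.1. The design fixed before the data were examined allowed for counts or FPKM; its threshold of 5 FPKM for named genes was applied as 5 TPM. The named genes were SlLBD40, up to 10 called genes per direction with the largest changes, non-overlapping groups, a mean of at least 5 TPM in the higher group and an informative description, and the 3 members of each gene list with the lowest adjusted p, whether or not they passed.

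The 24 gene lists were also fixed before the data were examined. Shorter lists were written as gene identifiers from memory, each with a keyword, and 27 entries whose description in the table lacked the keyword were dropped, with 3 more not found. Of the dropped entries, 19 proved to be described under another name of the same gene; they were restored only in an added alternative. Larger lists took every gene whose description matched a pattern. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry.

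The scripts were tested on simulated data before use. With 18368 simulated genes, 200 of them changed, the knockout comparison called 0% of genes changed 2-fold, 34.3% of those changed 4-fold and 77.3% of those changed 8-fold, and 5 genes that had not been changed. With no gene changed it called 0. Simulated genes were independent of one another, unlike real ones. Of the simulated lists, the 1 shifted list was called by each of the 3 list tests and 0 of the others.

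The alternatives were median-ratio scaling of the libraries, no filter on low values, a filter of 5 TPM, a pseudocount of 0.1, limma's robust option, and leaving out each library in turn. Count-based alternatives did not apply to TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.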

Results

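Transcript levels were measured by RNA-seq in fruit of the dwarf tomato cultivar Micro-Tom at 25 days after anthesis, in 3 wild-type libraries and 3 libraries from a line in which SlLBD40 was knocked out. SlLBD40 encodes a LATERAL ORGAN BOUNDARIES domain transcription factor. Between 17352 and 18693 genes reached 1 TPM in each library, the lowest number being that of knockout 3. The 10 most abundant transcripts took between 9.07% and 16.7% of the total. Across genes, the log2(TPM + 1) values of 2 libraries correlated with Pearson's r between 0.875 and 0.926 within wild type, between 0.869 and 0.941 within the knockout, and between 0.787 and 0.910 across genotypes. Genes are not independent replicates.

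The labels give no identifier for SlLBD40. It was taken, from memory and before the data were examined, as Solyc02g085910, described in the table as a LOB domain-containing protein. That gene stood at 1.57, 5.35 and 1.90 TPM in wild type 1 to 3 and at 0.77, 2.51 and 3.85 TPM in knockout 1 to 3. Its log2 fold change of −0.22 (SE 0.51, 95% interval −1.43 to 0.99, limma adjusted p = 0.875, n = 3 per genotype) was within the spread between libraries, and its sign changed when single libraries were left out, between −0.54 and 0.19. The transcript level therefore does not check the genotype labels, and a small edit in a coding sequence need not lower it. A different gene, Solyc05g009320, bears the description LOB domain-containing protein 40, and which of them was edited is not settled here. It was chosen after its values were seen and stood at 3.41, 0.79 and 1.53 TPM in wild type and 1.23, 1.51 and 0.61 TPM in the knockout (adjusted p = 0.692).

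The comparison of the genotypes asked which transcripts differ between wild-type fruit and fruit labelled as SlLBD40 knockout. The prefix of the sample titles, and the sequencing lane where the labels give one, differ between the genotypes, so no difference reported can be told apart from what these mark. The most distinct genes were read in 1 genotype and listed at 0 in the other. A glutathione S-transferase gene (Solyc12g044530), of a family that conjugates glutathione to other compounds, was listed at 0 in all 3 wild-type libraries and at 30.8, 18.7 and 25.2 TPM in the knockout (adjusted p = 0.00764). A chloroplastic or mitochondrial isoleucine-tRNA ligase gene (Solyc03g083080) was listed at 0 in wild type and at 24.1, 13.4 and 25.0 TPM in the knockout (adjusted p = 0.0114). Solyc07g016117, described by its likeness to a human tumour antigen, was listed at 0 in wild type and at 11.4, 10.9 and 12.9 TPM (adjusted p = 0.0114). In the other direction, an FBD and leucine-rich repeat domain gene (Solyc04g078075) stood at 28.7, 32.2 and 37.1 TPM in wild type and was listed at 0 in the knockout (adjusted p = 0.00403). A transferase gene with a chloramphenicol acetyltransferase-like domain (Solyc10g008650) stood at 11.04, 8.50 and 14.9 TPM in wild type and was listed at 0 in the knockout (adjusted p = 0.0156).

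Among genes read in both genotypes, the ripening-regulated DDTFR18 (Solyc04g074850) rose from 6.55 ± 1.31 TPM in wild type to 82.2 ± 32.8 TPM in the knockout (SD, n = 3; log2 fold change 3.38, SE 0.37, adjusted p = 0.0336). A peptidylprolyl isomerase gene (Solyc03g119150), of a family that assists protein folding, rose from 7.14 ± 1.31 to 44.2 ± 7.10 TPM (log2 fold change 2.47, SE 0.26, adjusted p = 0.0297). A DC1 domain gene (Solyc05g005460) fell from 55.9 ± 17.5 to 1.99 ± 1.26 TPM (log2 fold change −4.28, SE 0.39, adjusted p = 0.0177). The plasma membrane aquaporin PIP2.1 (Solyc09g007770), a water channel, fell from 16.9 ± 4.12 to 0.833 ± 0.392 TPM (log2 fold change −3.28, SE 0.32, adjusted p = 0.0228). A calcium-binding EF-hand gene (Solyc07g062700) fell from 226 ± 31.0 to 26.8 ± 9.08 TPM (log2 fold change −3.08, SE 0.31, adjusted p = 0.0229). The cyclin gene cyclinJ18 (Solyc04g078500) stood at 11.6, 23.2 and 15.3 TPM in wild type and at 0, 0 and 0.5 TPM in the knockout (adjusted p = 0.0181).

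In all, 8 genes were higher and 9 lower in the knockout of 18368 tested by limma, and all 17 changed at least 2-fold; 7 of them were listed at 0 throughout 1 genotype. The remaining 6 called genes had no informative description, 2 of them noncoding. At an unadjusted p under 0.05, 1146 genes were higher and 2070 lower, where 918 in total would be expected by chance. Median-ratio scaling turned this split into 1700 higher and 1738 lower and moved the median log2 fold change of all genes by 0.10, from −0.087 to 0.016. The groups did not overlap for 24.4% of genes, where chance gives 10%. Neither chance value allows for differences that many genes share. Other divisions of the 6 libraries into 3 and 3 gave 142 to 2106 genes at an unadjusted p under 0.05, against 3216 for the genotypes. The number of calls changed with each library left out. All 17 genes kept their sign, but this was fixed in advance, since their groups do not overlap. The log2 fold change ranged from −4.61 to −4.05 for the DC1 domain gene, from −3.43 to −3.10 for PIP2.1 and from 3.14 to 3.76 for DDTFR18. Without wild type 3 or without knockout 1 limma called 0 genes (957 higher and 1376 lower, and 689 higher and 1372 lower, at an unadjusted p under 0.05). Without wild type 1, wild type 2 or knockout 2 it called 11, 3 and 9, and without knockout 3 it called 16 higher and 7 lower. These fits kept the filter of all 6 libraries. With the filter applied again to the libraries left, an alternative chosen after seeing the data, 11 of the 17 genes could be tested. Limma then called 1 gene without knockout 3 and 0 without any other single library, with 2020 to 3522 at an unadjusted p under 0.05. Median-ratio scaling called 14 genes higher and 13 lower, 15 of them among the 17. With no filter on low values limma called 0 genes, with 3699 at an unadjusted p under 0.05.

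**Figure D1:**
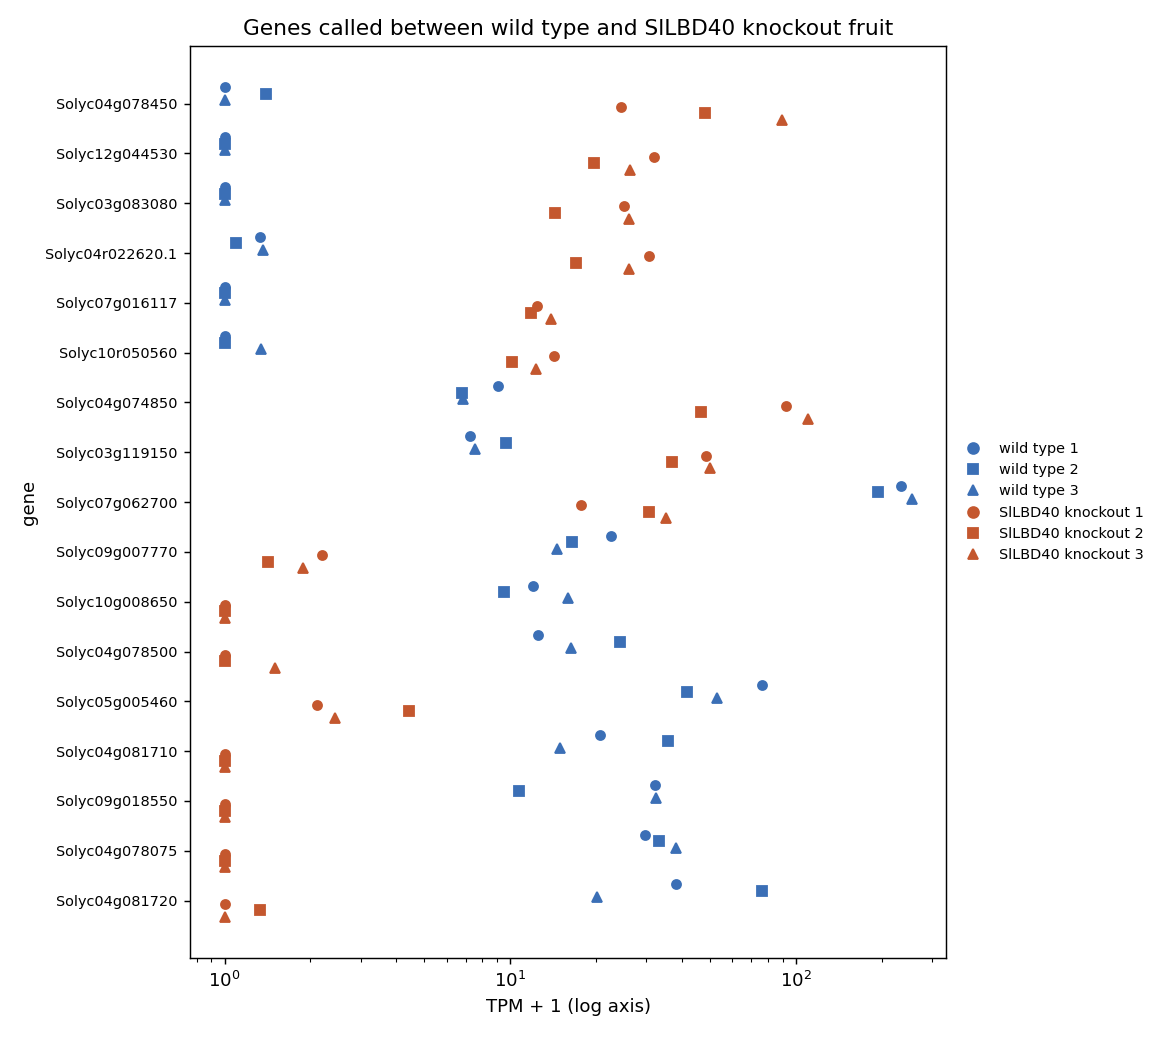
TPM + 1 on a log axis for the 17 genes called between genotypes, with 1 point per library and genes ordered by fitted log2 fold change; blue marks wild type and orange the SlLBD40 knockout. For every gene the 3 wild-type points lie apart from the 3 knockout points, and 7 genes lie at 0 TPM in all libraries of 1 genotype.

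Camera at its preset correlation called 5 of the 24 lists. Of the 10 divisions of the 6 libraries into 3 and 3, the real one included, 9 gave as many or more. Its calls below therefore do not by themselves set the genotypes apart. Genes for cytosolic ribosomal proteins, the protein parts of the ribosome, stood lower in the knockout as a list. Of 200 tested, 190 had a lower mean, with a median log2 fold change of −0.88 (camera adjusted p = 1.19e-32; adjusted p = 0.585 with an estimated correlation; fry adjusted p = 0.0383). The mean level of the list was 7.82 ± 0.0421 on the log2(TPM + 1) scale in wild type and 7.02 ± 0.184 in the knockout (SD, n = 3). Adjusted over the list alone, 132 fell and 0 rose, against 0 in either direction over all genes. The P0 gene Solyc05g054580 stood at 501 ± 108 TPM in wild type and 166 ± 17.0 TPM in the knockout. The S12 gene Solyc12g042650 stood at 417 ± 64.1 and 154 ± 26.5 TPM (SD, n = 3). The P3 gene Solyc07g009330 had a log2 fold change of −1.60 (SE 0.26). The count adjusted over the list alone fell to 0 under median-ratio scaling, to 97 and 95 without wild type 2 or wild type 1, and to 72 and 63 without wild type 3 or knockout 1. It was also 0 without both of the libraries rich in seed storage transcripts, wild type 1 and knockout 1, an alternative chosen after seeing the data. The list's median stayed between −0.76 and −0.99 in all of these.

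Genes of the photosynthesis apparatus stood higher in the knockout as a list. Of 70 tested, 55 had a higher mean, with a median log2 fold change of 0.67 (camera adjusted p = 2.09e-12; adjusted p = 0.585 with an estimated correlation). Adjusted over the list alone 18 rose and 0 fell, against 0 over all genes. A chlorophyll a-b binding protein gene (Solyc12g009200), of the light-harvesting antenna, rose over the list alone from 1.43 ± 0.741 to 12.0 ± 2.37 TPM. The photosystem II gene for psbY (Solyc10g077120) rose from 70.7 ± 11.9 to 206 ± 24.1 TPM (SD, n = 3). The photosystem II protein Z gene (Solyc11g050770) was listed at 0 in wild type and at 2.35, 2.02 and 2.15 TPM in the knockout. Wild type 1, with a list level of 5.26, lay among the knockout libraries (4.92 to 5.62) and apart from wild type 2 and 3 (4.13 and 4.21). The count of 18 became 33 without wild type 1, 5 without wild type 2, 3 without wild type 3, 4 without knockout 1, 11 without knockout 2, 6 without knockout 3, 12 under median-ratio scaling and 7 with no filter, where the median was 0.26. Without both seed-rich libraries the count was 28. The median was 1.03 without wild type 1 and 1.17 without both seed-rich libraries.

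Genes of the cell cycle and histones stood lower as a list, with a median log2 fold change of −0.47 over 95 genes (camera adjusted p = 0.000532; adjusted p = 0.585 with an estimated correlation). Adjusted over the list alone 6 fell and 2 rose, against 0 over all genes. The DNA replication licensing gene MCM7 (Solyc01g079500) fell over the list alone from 10.7 ± 2.54 to 1.41 ± 0.297 TPM, histone H3 (Solyc04g081145) from 98.2 ± 11.7 to 40.2 ± 6.17 TPM and histone H2A (Solyc09g074300) from 10.98 ± 5.96 to 0.987 ± 0.687 TPM (SD, n = 3). Both genes that rose are described as histone H1, a linker histone. The number that rose over the list alone was 1 under median-ratio scaling or with the seed marker level as a covariate. It was 0 with no filter or without wild type 1, wild type 2, knockout 1, knockout 2 or both seed-rich libraries. The camera call was lost without both seed-rich libraries (median −0.43, adjusted p = 0.129). The 6 that fell over the list alone became 24 without wild type 3, 1 without wild type 2 and 1 under median-ratio scaling. That count was 3 with no filter, and 0 without wild type 1, knockout 1, knockout 2 or both seed-rich libraries.

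Cell wall families stood lower as a list, with a median log2 fold change of −0.55 over 99 genes (camera adjusted p = 0.00406; adjusted p = 0.870 with an estimated correlation). Adjusted over the list alone 9 fell and 0 rose, against 0 over all genes. The β-galactosidase gene TBG6 (Solyc02g084720), which trims pectin side chains, fell over the list alone from 108 ± 37.3 to 9.77 ± 6.11 TPM, and a xyloglucan endotransglucosylase gene (Solyc09g008320) from 157 ± 61.2 to 12.0 ± 7.15 TPM (SD, n = 3). A pectate lyase gene (Solyc05g014000) ranged from 30.2 to 365 TPM in wild type and from 0.36 to 6.47 TPM in the knockout. The camera call was lost with no filter (median −0.10, adjusted p = 0.165), with the filter of 5 TPM (−0.43, 0.0845), without knockout 1 (−0.57, 0.131) and without both seed-rich libraries (−0.51, 0.407). Without wild type 2 the median was −0.87. The 9 that fell over the list alone became 24 without wild type 2, 4 without wild type 1 and 6 with the filter of 5 TPM. That count was 2 without wild type 3, knockout 1 or knockout 3 or with no filter, and 1 without both seed-rich libraries.

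The carotenoid pathway stood higher as a list, with a median log2 fold change of 0.66 over 15 genes (camera adjusted p = 0.00406; adjusted p = 0.585 with an estimated correlation). Adjusted over the list alone 1 gene rose, against 0 over all genes. This was violaxanthin de-epoxidase (VDE), an enzyme of the xanthophyll cycle, from 15.3 ± 3.57 to 45.9 ± 1.10 TPM (SD, n = 3). Phytoene desaturase (PDS) stood at 36.6 ± 5.02 and 63.8 ± 14.6 TPM, and carotenoid isomerase (CRTISO) at 26.2 ± 5.53 and 47.9 ± 12.1 TPM. Without knockout 3 the median was 0.30 and the camera call was lost (adjusted p = 0.0918). Without wild type 1 or knockout 1 the median was 0.40 or 0.41. Without both seed-rich libraries it was 0.41 and 10 of the 15 genes had a higher mean, but 0 rose adjusted over the list alone.

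**Figure D2:**
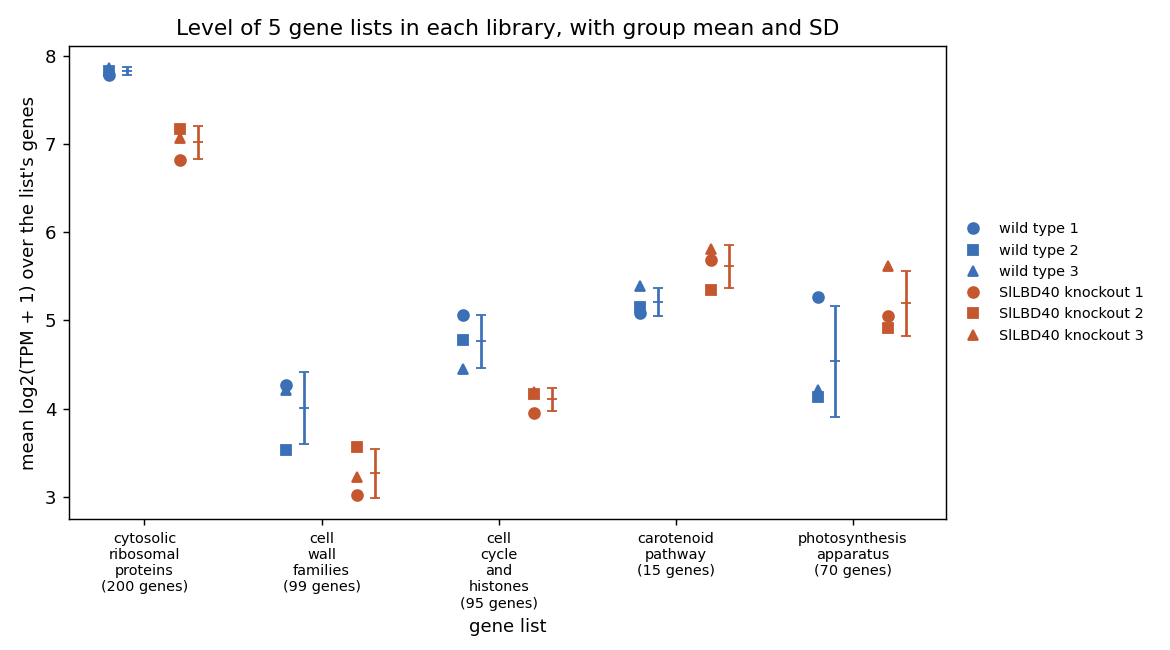
Mean log2(TPM + 1) over the genes of each of the 5 lists called by camera, with 1 point per library and bars for the group mean ± SD (n = 3); blue marks wild type and orange the SlLBD40 knockout. The wild-type and knockout points of the ribosomal list are separated, at 7.82 ± 0.0421 and 7.02 ± 0.184, while wild type 1 lies among the knockout libraries for photosynthesis.

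The other 19 lists were not called by camera with all 6 libraries, and 0 of their genes passed over all genes. Members that passed over the list alone are named with their list, and the other lists had 0. Ripening regulators had a median log2 fold change of 0.35 over 7 genes (adjusted p = 0.518), and −0.16 without wild type 1. Of the list's 10 entries, 3 had been dropped because their descriptions lacked the keyword, and RIN was among those dropped. NOR, a NAC transcription factor needed for ripening, stood at 3.29, 28.9 and 29.0 TPM in wild type and at 80.4, 54.0 and 402 TPM in the knockout (adjusted p = 0.190). MADS1 stood at 95.8 ± 50.5 and 56.9 ± 27.8 TPM, and AP2a at 41.2 ± 12.3 and 84.3 ± 61.0 TPM. Of the ethylene genes, ACO1 stood at 1408 ± 786 TPM in wild type and 485 ± 236 TPM in the knockout (adjusted p = 0.207). ACO4 stood at 42.6 ± 13.9 and 19.6 ± 10.2 TPM and EIL2 at 23.6 ± 2.94 and 16.7 ± 2.18 TPM. The list's median was −0.19 (adjusted p = 0.518), and 0.13 without wild type 3. Fruit softening enzymes had a median of 0.41 over 12 genes (adjusted p = 0.688; camera up, fry down), but 0.11 without knockout 2 and 0.98 without knockout 1. TBG6 was the 1 gene that fell adjusted over the list alone. XTH5 ranged from 17.1 to 155 TPM in wild type and from 0.59 to 10.7 TPM in the knockout, and MAN4 from 0 to 5.92 and from 6.39 to 672 TPM.

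Hormone lists were not called either. For jasmonate the median was −0.91 over 12 genes (adjusted p = 0.177). Camera did call this list without wild type 2 (−1.23, adjusted p = 0.0114) or knockout 3 (−0.95, 0.0090). Allene oxide cyclase (AOC), a biosynthetic enzyme, fell adjusted over the list alone, from 305 ± 185 to 50.6 ± 21.8 TPM. AOS1 stood at 6.76 ± 2.95 and 2.24 ± 1.24 TPM and AOS2 at 23.8 ± 12.1 and 9.76 ± 0.925 TPM. For gibberellin the median was −0.80 over 3 genes (adjusted p = 0.421), but −2.01 without knockout 3 and −0.21 without knockout 1. The catabolic GA2ox4 fell over the list alone from 9.06 ± 7.16 to 0.367 ± 0.523 TPM. For abscisic acid and drought the median was 0.42 and the mean −0.31 over 3 genes (adjusted p = 0.922; camera and fry up). With renamed entries restored, an alternative chosen after seeing the data, the median was −0.73. TAS14, an abscisic acid and stress-inducible gene, fell over this list of 3 genes alone, from 503 ± 452 to 61.5 ± 51.5 TPM (limma adjusted p = 0.159 over all genes). Its groups overlapped, with wild type 1 at 116 TPM and knockout 3 at 121 TPM. Auxin response families had a median of −0.21 over 87 genes (adjusted p = 0.331). An auxin response factor gene (Solyc12g006350) stood at 172 ± 110 TPM in wild type and 28.5 ± 5.17 TPM in the knockout. LBD transcription factors, the family of SlLBD40, had a median of −0.12 over 9 genes (adjusted p = 0.922), and 0.0086 and 0.040 without wild type 2 or knockout 1. Solyc02g067800 fell over the list alone from 33.1 ± 24.9 to 5.05 ± 0.777 TPM. LOB domain-containing protein 41 (Solyc03g119530) stood at 136 ± 64.5 and 209.9 ± 5.51 TPM.

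Metabolic and surface lists showed the following. Ascorbate genes had a median of −0.30 over 17 genes (adjusted p = 0.346), with APX2, an ascorbate peroxidase, at 189 ± 2.21 TPM in wild type and 110.5 ± 14.7 TPM in the knockout (adjusted p = 0.132). Sugar and starch genes had a median of 0.090 over 6 genes (adjusted p = 0.518), with the starch branching enzyme SBE at 23.5 ± 2.02 and 38.1 ± 5.13 TPM. That median was −0.16 without wild type 2 or with no filter, −0.054 without knockout 1 and −0.24 with renamed entries restored. Flavonoid genes had a median of 0.17 and a mean of −0.0029 over 8 genes (adjusted p = 0.887; camera up, fry down), with CHI1 at 19.1 ± 8.97 and 5.26 ± 3.71 TPM. The flavonoid median was −0.062, −0.073 and −0.81 without wild type 2, wild type 3 and knockout 3. Steroidal glycoalkaloid genes had a median of −0.95 over 7 genes (adjusted p = 0.331), with GAME31 at 440 ± 178 and 216 ± 44.7 TPM. Their median was 0.19 without wild type 1, whose list level was 5.97 against 2.94 and 3.54 in wild type 2 and 3. Without wild type 2 camera called this list (−1.30, adjusted p = 0.0182). Cuticle genes had a median of −0.64 over 6 genes (adjusted p = 0.331), and 0.40 without knockout 3, whose list level was 1.29 against 3.64 and 3.97 in knockout 1 and 2. The cutin synthase CD1 stood at 75.4, 3.65 and 7.05 TPM in wild type and at 0.24, 1.15 and 0 TPM in the knockout. Heat shock genes and chaperones had a median of 0.068 over 198 genes (adjusted p = 0.0949), and −0.020 and −0.023 without wild type 1 or knockout 1. Over the list alone a class IV heat shock protein gene (Solyc03g113930) rose from 0.993 ± 0.271 to 41.9 ± 30.9 TPM and a dnaJ chaperone gene (Solyc10g079090) fell from 30.4 ± 3.93 to 7.84 ± 1.29 TPM. Defence genes and protease inhibitors had a median of −0.089 and a mean of 0.20 over 75 genes (adjusted p = 0.887; camera up, fry down). Over the list alone PR1 (Solyc02g065470) fell from 249.5 ± 51.7 to 70.0 ± 6.55 TPM and a defensin gene (Solyc07g007750) from 1132 ± 465 to 258 ± 63.5 TPM. MADS, NAC and ERF transcription factors had a median of 0.028 over 120 genes (adjusted p = 0.421). It was −0.11, −0.042 and −0.056 without wild type 1, knockout 1 and knockout 2, −0.025 with no filter and −0.058 with a pseudocount of 0.1.

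Markers of other tissues differed between libraries of 1 genotype. The seed list had a median of 0.15 over 79 genes (adjusted p = 0.518; camera up, fry down). It was −0.088, −0.20 and −0.17 without wild type 2, wild type 3 and knockout 1, and −0.019 with no filter. Camera called the list without wild type 1 (0.15, adjusted p = 0.0155) and without both seed-rich libraries (0.13, 0.00126). Its mean level was 4.83 in wild type 1 and 4.53 in knockout 1 against 3.35, 3.42, 3.80 and 3.57 in wild type 2 and 3 and knockout 2 and 3. A caleosin gene of this list (Solyc01g005400), an oil body protein, rose over the list alone from 1.74 ± 0.442 to 73.9 ± 62.4 TPM. The 11S globulin gene Solyc09g072560 stood at 396, 0.17 and 0.03 TPM in wild type and 824, 10.5 and 0 TPM in the knockout. Vascular and lignin families had a median of −0.20 over 37 genes (adjusted p = 0.421). The locule and ovule list had a median of −0.27 over 5 genes (adjusted p = 0.922), and 0.16 and 0.11 without wild type 3 or knockout 1. The MADS-box gene MBP3 stood at 37.4, 13.1 and 20.2 TPM in wild type and at 2.13, 58.3 and 0.23 TPM in the knockout. These seed levels are a measured difference beside each group of genes above; the counts without both seed-rich libraries are 0 called genes, with 538 higher and 1088 lower at an unadjusted p under 0.05.

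**Figure D3:**
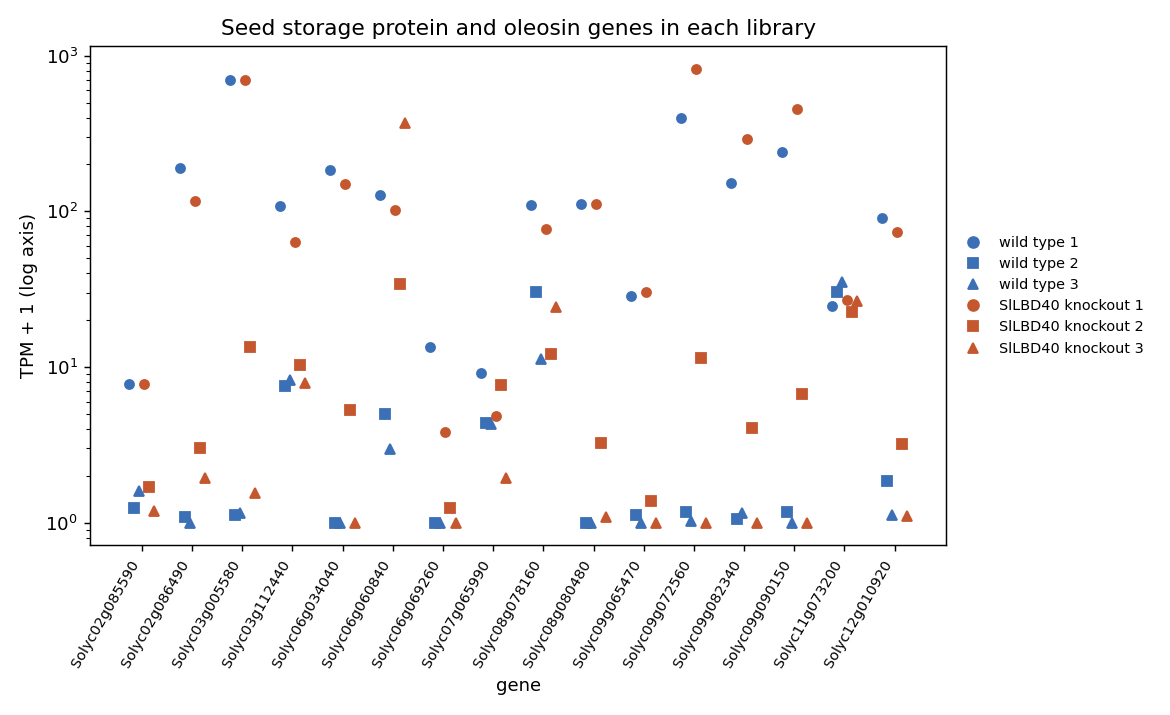
TPM + 1 on a log axis for 16 genes described as seed storage proteins or oleosins, a set chosen after the data were seen, with 1 point per library; blue marks wild type and orange the SlLBD40 knockout. For 13 of the 16 genes the highest values are those of wild type 1 and knockout 1.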

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

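The added alternatives, chosen after seeing the data, were leaving out both seed-rich libraries, the seed marker level as a covariate, restoring renamed list entries, and leaving out single libraries with the filter on low values applied again. All other settings were fixed before the data were examined. All 17 called genes kept their sign in every setting where all 17 could be tested. With libraries left out, another filter, another pseudocount or the robust option this was fixed in advance, since their groups do not overlap. Limma's robust option and the pseudocount of 0.1 called 17 and 16 genes, of which 17 and 15 were among the original calls, the 5 TPM filter called 22 including all 17. The seed covariate called 17, of which 14 were shared.

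Median-ratio scaling called 27 genes, 14 higher and 13 lower, 15 of them shared; the cause was not tested. With no filter 0 were higher, 0 lower and 0 changed 2-fold, with 27712 genes tested. Without both seed-rich libraries 0 were higher, 0 lower and 0 changed 2-fold (smallest adjusted p 0.155, 1626 at an unadjusted p under 0.05). Leaving out single libraries gave 0 to 16 genes higher, 0 to 7 lower and 0 to 23 changed 2-fold. In those fits the filter used all 6 libraries. A version with the filter applied again to the 5 libraries left, which drops genes expressed only in the smaller group so that 11 of the 17 genes could be tested, gave 0 higher, 0 or 1 lower and 0 or 1 changed 2-fold, with 2020 to 3522 genes at an unadjusted p under 0.05. Both versions were seen before the first was kept as the main form of this alternative, and the first is the more favourable to the calls.

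The number of called lists was 5, and 4 to 7 when single libraries were left out. With an estimated correlation in camera it was 0. The ribosomal list (median −0.88), photosynthesis (0.67), cell cycle and histones (−0.47) and carotenoids (0.66) had an adjusted p of 0.585, and cell wall families (−0.55) of 0.870. With fry it was 1, the ribosomal list; carotenoids (0.66, adjusted p = 0.208), photosynthesis (0.67, 0.216), cell cycle (−0.47, 0.0768) and cell wall families (−0.55, 0.216) were lost. Cell wall families also lost the camera call with no filter (−0.10), with the 5 TPM filter (−0.43) and without both seed-rich libraries (−0.51), and ranged from −0.87 to −0.46 over single libraries left out. Cell cycle and histones lost it without both seed-rich libraries (−0.43). Carotenoids ranged from 0.30 to 0.76 over single libraries. The causes were not tested.

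Changes of sign were found only in results that were not called with all 6 libraries. Over single libraries left out, the log2 fold change of SlLBD40 ranged from −0.54 to 0.19, F3primeH from −0.075 to 1.02, GA20ox3 from −0.67 to 1.08 and TTS2 from −1.35 to 0.070. List medians ranged from −0.38 to 0.040 for LBD factors, −0.11 to 0.097 for MADS, NAC and ERF factors, −1.26 to 0.40 for cuticle, −0.45 to 0.13 for ethylene. They ranged from −0.81 to 0.49 for flavonoids, −0.023 to 0.18 for heat shock, −0.85 to 0.16 for locule and ovule. They ranged from −0.16 to 0.55 for ripening regulators, −0.20 to 0.21 for seeds, −1.30 to 0.19 for glycoalkaloids and −0.16 to 0.20 for sugar and starch. Without a change of sign, medians of lists not called ranged from −2.01 to −0.21 for gibberellin, 0.11 to 0.98 for fruit softening and 0.24 to 0.58 for abscisic acid. The ranges were −0.36 to −0.18 for auxin, −0.38 to −0.20 for ascorbate, −0.22 to −0.035 for defence and −0.42 to −0.22 for vascular families. With no filter, sugar and starch became −0.16, seeds −0.019 and MADS, NAC and ERF factors −0.025, and the last −0.058 with a pseudocount of 0.1. Without both seed-rich libraries INVINH1 became −0.027, ANS −0.17, AGL11 0.37, ripening regulators −0.068, sugar and starch −0.19, heat shock −0.10 and MADS, NAC and ERF factors −0.17. With the seed covariate seeds became −0.062 and MADS, NAC and ERF factors −0.027. With renamed entries restored, sugar and starch became −0.24 and abscisic acid −0.73. Among lists not called with all 6 libraries, camera called seeds without both seed-rich libraries (0.13, adjusted p = 0.00126) and without wild type 1 (0.15, 0.0155). It called jasmonate without wild type 2 (−1.23, 0.0114) or knockout 3 (−0.95, 0.0090), and glycoalkaloids without wild type 2 (−1.30, 0.0182). The alternatives that need counts or FPKM were not run. No paired analysis was possible because the columns' numbers are not those of the samples. TPM keeps no depth, so what depth limits cannot be given.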

Other observations

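The families and genes in the next 2 paragraphs were chosen after their values were seen. The count of gene lists under other splits of the libraries and the setting of median-ratio scaling were fixed before the data were examined. The other tests in this part, and the use of that scaling to weigh an explanation, were chosen after the results they bear on were seen.

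Genes described in the table as DNA helicase, or by an MCM name, were mostly lower in the knockout. Of 8 such genes 7 had a lower mean, with a median log2 fold change of −2.32, and 0 were called over all genes. They include MCM7, a DNA replication licensing factor, and an MCM10 homolog (Solyc01g111550), a replication factor that is not a helicase of the MCM family. The DNA helicase gene Solyc11g040120 stood at 32.2 ± 9.47 TPM in wild type and 5.28 ± 1.09 TPM in the knockout, and Solyc01g110130 at 20.2 ± 9.68 and 1.85 ± 0.718 TPM (SD, n = 3). Of 19 aquaporin genes 12 had a lower and 7 a higher mean log2(TPM + 1) (median −0.48), and PIP2.1 was the 1 called over all genes. Among the 7, Solyc06g072130 had a lower mean TPM in the knockout, 10.6 against 17.1. PIP1.7 (Solyc03g096290) stood at 420 ± 411 TPM in wild type and 2.77 ± 3.21 TPM in the knockout. Of 21 small heat shock protein genes 17 had a higher mean (median 0.91), and of 6 elongation factor 1-alpha genes 5 a lower one (median −0.92). Of 11 glyceraldehyde-3-phosphate dehydrogenase genes 7 had a higher mean (median 0.14), and the 2 genes described as dehydrins a lower one (median −1.39). Of these 2, Solyc02g084840 had a log2 fold change of −0.52 (SE 1.08), within the spread between libraries. In these last 4 families 0 genes were called over all genes. No p-value is given for a family, since each was picked after its values were seen. Under median-ratio scaling the numbers of lower and of higher means were the same in each family, with medians of −2.22, −0.36, 1.02, −0.80, 0.26 and −1.28 in the order given.

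Some ripening genes had their highest value in knockout 3. E8 stood at 6454 TPM there against 449 to 1822 TPM in the others. RIN was also higher in each knockout library than in any wild-type library. It stood at 1.53, 19.7 and 8.14 TPM in wild type and at 27.3, 20.85 and 113 TPM in the knockout (limma adjusted p = 0.228). PSY1 stood at 643 TPM in knockout 3 against at most 175 TPM in the others. The ethylene receptor gene NR stood at 130 TPM in knockout 3 and 119 TPM in wild type 3. CYCB was highest in wild type 2, at 2.59 TPM, and GLK2 in wild type 3, at 3.63 TPM. GAME4, of glycoalkaloid synthesis, stood at 112 TPM in wild type 1 and at 5.76 TPM or below in the others.

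With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split called 17 genes, 8 higher and 9 lower, and the highest of the other splits 1; it was the 1 split with so many for each of these counts and for genes changed 2-fold. For gene lists called by camera the real split gave 5, and 9 of the 10 splits gave as many or more, with 13 as the highest of the others. With an estimated correlation in camera, each of the 10 splits called 0 lists.

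A first pattern is genes on in 1 genotype and off in the other: with at least 5 TPM in all 3 libraries of 1 genotype and at most 0.5 TPM in all of the other there were 14 such genes, 8 on in wild type and 6 on in the knockout, while the highest of the other splits had 12 and the real split was the 1 of 10 with so many. Of the 12 coding genes, 2 had an adjacent coding gene that moved the other way by at least 0.5 times as many TPM (16.7%, against 30.0% of expressed coding genes). For most of them this argues against reads assigned to an adjacent coding gene of like length. Gene length was not used, and the same reads give fewer TPM in a longer gene. Noncoding neighbours were left out and TPM does not count reads, so reads assigned to those were not tested. Failed estimates stay open in part. Independent failures at the rate of lone low values would give 8.57e-06 such genes, too few for the 14, while failures shared between libraries were not tested. The other 9 splits together hold 29 such genes, which independent failures would not give either. Those genes need not all be failures, and their causes were not tested. The split of wild type 1, knockout 1 and knockout 2 from the rest holds 12. The seed storage gene Solyc09g072560 meets the rule there, at 396, 824 and 10.5 TPM against at most 0.17 TPM. A chromosome segment that differs between the parent lines may account for part of them, beside an effect of the knockout itself or of fruit stage or lane, which were not separable: 5 of the coding genes lie on chromosome 4 within 360 consecutive coding genes, and random draws gave as many near neighbours in shares of 0.0006, 0.0054, 0.0342 and 0.141 of 10000 draws for windows of 50, 100, 200 and 400 genes, so the answer changes with the window. All windows were chosen after the positions were seen.

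A second pattern is lower ribosomal protein and higher photosynthesis transcripts in the knockout. Wild type 1 and knockout 1 do not alone carry these differences. Without both, the list medians were −0.76 for ribosomal genes, from −0.88, and 1.17 for photosynthesis, from 0.67. Less the median of all genes, they went from −0.80 to −0.55 and from 0.76 to 1.38. Seed transcripts stayed uneven among the libraries left. The 16 seed markers had a median of 5.0 TPM in knockout 2 and at most 0.17 TPM in the others left. How much seed RNA adds is therefore open. With median-ratio scaling the list medians were −0.76 and 0.78. Median-ratio scaling nevertheless ended every ribosomal call over the list alone. Under it the difference in list level went from −0.81 to −0.69, and the SD between knockout libraries from 0.184 to 0.357. The median SD of a gene went from 0.254 to 0.360. The cause of the lost calls was not tested. Fruits of different developmental stage may contribute and cannot be told apart from genotype: in 0 of the 2 genotypes was the library with the highest ripening regulator level the lowest in ribosomal level, which 3 libraries cannot decide. The sequencing lane is confounded with genotype, and the knockout itself remains among the open explanations.

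The third pattern is seed transcripts in 1 library of each genotype. An exchange of labels between these libraries would leave 1 of them in each genotype, and the tables argue against it: of the 50 genes that best separated the genotypes in the other 4 libraries, 32 placed both libraries on the side of their own genotype and 2 on the other side. Seeds within the sampled fruits are a candidate source that stays open. In the seed list fixed before the data were examined, 79 genes were tested. Of these, 18 had wild type 1 and knockout 1 as their highest libraries. Without the 15 seed storage and oleosin genes that prompted the test 7 of 64 did, against 9 for the highest of the other pairs. That second count cannot decide the source, since it leaves out the seed storage genes themselves. The genes left include a late embryogenesis abundant hydroxyproline-rich glycoprotein gene (Solyc08g082470). The 16 seed markers, chosen after the data were seen, had medians of 109 TPM in wild type 1 and 88.4 TPM in knockout 1. In the other libraries their median was at most 5.0 TPM. The seed storage gene Solyc03g005580 reached 702 and 697 TPM in these libraries and 12.4 TPM or less in the others.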
